A study of Homo sapiens with 84 samples.

How the data were processed

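H3K27ac, the acetylation of lysine 27 of histone H3 that marks active promoters and enhancers, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in 28 established cell lines of diffuse large B-cell lymphoma (DLBCL). Each line gave 3 samples, which were a precipitate with an antibody from Active Motif, a precipitate with an antibody from Diagenode, and an input library without antibody, for 84 samples in total. The series text speaks of 29 lines, and 28 were analysed here. Per the labels' protocols, log-phase cells were fixed for 10 min in formaldehyde at 1%, and their chromatin was sonicated to fragments of 200 to 500 bp. Libraries were made from 3 ng of DNA and sequenced as 150-bp read pairs, with a stated average of 25000000 reads per sample. The depth of each library is unknown from the peak lists, so no counting interval or detection floor could be given for a region.

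The submitters' processing notes name the build hg19 and the tools CASAVA 1.8, Bowtie2 2.1.0 and SAMtools 0.1.19, without their roles. The peak caller is not given in the sources used here, and the tags p15 and md100 in the file headers are not explained there. The authors deposited 1 peak list for each precipitate, 56 in all, called per sample and not on pooled samples. Per the file headers, each list was called against the input of its own line, and the 2 lists of a line used the same input in 28 of 28 lines. A list holds positions and peak names, with no score, height, fold enrichment or p-value. The shortest peak spanned 99 bp and the smallest gap between neighbouring peaks was 101 bp in the deposited lists. No list held duplicated rows and no lists were identical. The input samples had no processed list and entered no comparison.

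The Diagenode list of SUDHL6 ended after chromosome 7, the last in its file order, and held no peaks on chromosomes 8, 9 and X. Those chromosomes were treated as not measured in SUDHL6 for both antibodies, which left 27 lines there. Chromosomes 1 to 22 and X were used throughout. Starts were read as counted from 0 and are printed counted from 1, on hg19. An annotation of hg19 was not used here, and the gene table at hand, on GRCh38.p14, belongs to another build, so regions are named by position and carry no gene name.

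From the lists, the number of peaks, the covered sequence (the summed width of the peaks) and the median peak width were computed for each library. The overlap of 2 lists was their Jaccard index, the bases in both lists divided by the bases in either. Overlapping peaks of all 56 lists were merged into regions, and a list detected a region when it shared at least 1 base with it. Clustered domains were obtained by joining the peaks of a list over gaps up to 12 kb, ranking the joined intervals by covered bases and keeping those beyond the point where the scaled rank curve has a slope of 1. A line held a domain where the domains of its 2 lists intersected, and overlapping intersections over lines formed a locus.

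Each line has 1 library per antibody, so the lines were the replicates of the antibody comparison and the 2 antibodies were the repeat measurements of a line. The labels do not state that the 2 precipitates came from separate cultures, so the spread between them may be technical. Pairing rested on the cell line named in the labels, and was checked by the overlap of lists given in the report. Differences between antibodies in peaks and covered sequence were tested with a two-sided sign-flip permutation test within lines. The overlap of lists was tested by a two-sided permutation of the pairing. Both used 100000 resamples, whose smallest possible p is 1e-05. Regions were tested with the exact McNemar test where at least 6 lines had a peak with only one antibody, with Benjamini-Hochberg adjustment and a threshold of 0.05. Windows of 20 kb with a peak in any list were tested for agreement of the antibodies over lines with a one-sided permutation test of the pairing of lines, 100000 resamples each, on the sum over lines of the products of the covered lengths with the 2 antibodies. The adjustment and threshold were the same.

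The design fixed before the data were examined assumed a genome annotation. The comparisons of promoters with distal regions, of gene lists, and of genes by their distance to a domain were therefore not computed. The fixed windows of 20 kb took the place of windows around gene starts, and were chosen after the data were seen. Filters by the caller's score used peak width in its place. By the fixed rule, the text names the 5 regions with the most one-sided line counts in each antibody direction, the 20 windows past the threshold with the largest SD between lines, and the 10 clustered loci found in the most lines. Other regions named in the text were chosen after their values were seen. Library pools were read from the file names, and 3 pools held libraries of both antibodies.

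The tests were checked on simulated data before use. For regions, 200 of 20000 simulated regions were given different detection rates. The test of regions recovered 75% of them at rates of 20% and 80% and 0% at rates of 35% and 65%, with 0 false calls in each case. For windows, 200 of 20000 were given an SD between lines equal to 1 or 2 times the SD between antibodies. The test of windows recovered 13.5% and 99.5% of them, with 2 and 10 false calls. In the data, 51276 of 63684 windows and 8905 of 9475 tested regions passed, which makes the adjusted threshold more lenient than in the simulations. Simulated windows also had peaks in at least 5 lines with each antibody. The rates of recovery and false calls therefore do not describe the tests as applied to the data. The alternatives tried were stricter lists, equal list lengths, autosomes only, other merging and detection criteria, other pools, other window and joining distances, no pairing, and leaving out lines. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0, and plots used matplotlib 3.10.9.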

Results

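H3K27ac was mapped in 28 cell lines derived from DLBCL, an aggressive lymphoma of mature B cells. Each line was precipitated with an Active Motif and a Diagenode antibody against the same mark. The 56 peak lists held 2059256 peaks in the deposited files. On the chromosomes used, the Active Motif lists held between 18425 and 46340 peaks and the Diagenode lists between 27670 and 50160. The lowest Diagenode count was that of SUDHL6, whose list ended early and was used on 20 chromosomes, and the lowest on all 23 was 33360 in LY18. Read depth per library is unknown, and a list gives the position of a peak but not its height. The labels assign the lines to no subtype, so lines were compared one by one. All positions are on hg19.

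The first comparison asked whether the 2 antibodies returned lists of the same size. The Diagenode antibody gave more peaks in 28 of 28 lines, with 40894 ± 5446 peaks per list (SD, n = 28) against 32409 ± 6529 with the Active Motif antibody. The mean difference within lines was 8486 ± 4025 peaks (p = 1e-05, the smallest that 100000 resamples of the sign-flip permutation test can give). The covered sequence was larger with the Diagenode antibody in 27 of 28 lines, at 33.8 ± 4.35 Mb against 26.9 ± 6.27 Mb. The mean difference was 6.94 ± 4.50 Mb (SD, n = 28, p = 1e-05 in the same permutation test, two-sided). RCK8 had the shortest Active Motif list, with 13.6 Mb covered against 32.0 Mb with the Diagenode antibody. SUDHL4 had the longest lists with both antibodies, at 44.2 Mb and 45.7 Mb. HLY1 was the line with the opposite sign, at 34.7 Mb with the Active Motif and 33.7 Mb with the Diagenode antibody, and HBL1 had nearly equal values of 30.4 and 30.5 Mb. Peaks were also wider with the Diagenode antibody in 25 of 28 lines, where the median width averaged 482 ± 33.4 bp against 442 ± 37.3 bp (SD, n = 28).

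Antibody and library pool were largely confounded within lines, since only LY1 and SUDHL6 had both libraries in the same pool. The Active Motif libraries of 20 lines lay in pools without a Diagenode library. Pools 3 and 7, with 6 Diagenode libraries each, held no Active Motif library. In all lines but LY1 and SUDHL6, the paired differences above therefore do not separate the antibody from the pool. Within the 3 pools that held both antibodies, the mean difference over pools was 8876 peaks (exact permutation p = 0.015) and 7.26 Mb (exact permutation p = 0.019), from 8 Active Motif and 16 Diagenode libraries. The difference in covered sequence was 5.26 Mb in pool 2, 5.63 Mb in pool 6 and 10.9 Mb in the pool named EP. In pools 2 and 6 the libraries of the 2 antibodies came from different lines. The within-pool tests therefore drop the pairing and do not separate the antibody from the lines. The EP value includes the Diagenode list of SUDHL4 (45.7 Mb), whose Active Motif list (44.2 Mb) lay in pool 1. Within lines in EP, the difference was 9.51 Mb in LY1 and 3.75 Mb in SUDHL6 (20 chromosomes).

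**Figure D1:**
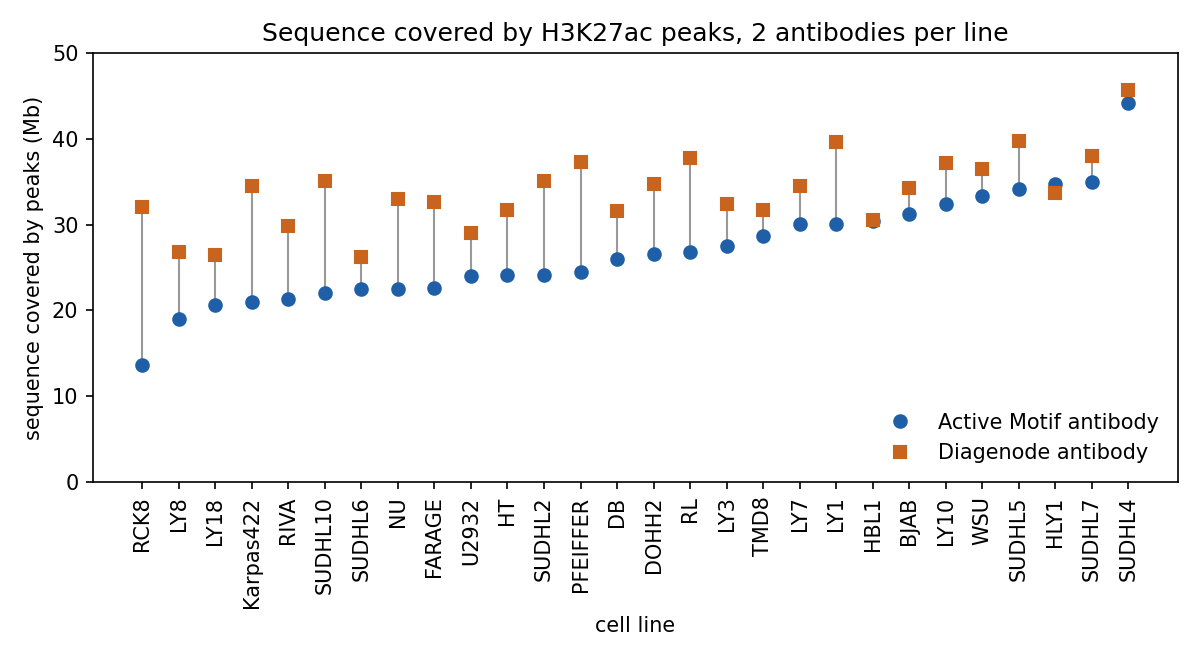
Sequence covered by H3K27ac peaks (Mb) in each of 28 cell lines, ordered by the Active Motif value. Circles are Active Motif lists, squares are Diagenode lists, and grey lines join the 2 lists of a line; the square lies above the circle in 27 of 28 lines.

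The second comparison asked whether a list resembled the other list of its own line more than the lists of other lines. The Jaccard index of the Active Motif and Diagenode lists averaged 0.653 ± 0.0686 within lines (SD, n = 28) and 0.264 ± 0.0702 between lines. The difference of 0.389 was beyond any of 100000 random pairings (permutation p = 1e-05). Same-line values ran from 0.422 in RCK8 to 0.748 in SUDHL4. An index cannot exceed the shorter covered length divided by the longer, and in RCK8 these were 13.6 and 32.0 Mb. RCK8 had 73 regions with only an Active Motif peak and 16069 with only a Diagenode peak. Its low value therefore follows the unequal lengths of its lists. Of the 56 lists, 55 were closest to the other list of their own line. The exception was the Diagenode list of SUDHL10, whose index was 0.588 with the Diagenode list of WSU and 0.584 with its own Active Motif list. The lists of SUDHL10 covered 22.1 Mb (Active Motif) and 35.0 Mb (Diagenode), and the Diagenode list of WSU covered 36.5 Mb. Unequal lengths lower the index that a pair can reach, so this exception does not show that SUDHL10 resembled WSU more than itself.

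Between lines, the closest other line was the same with both antibodies in 22 of 28 lines. The pairs with the highest mean index were SUDHL10 with WSU (0.482 with the Active Motif and 0.588 with the Diagenode antibody), SUDHL4 with WSU (0.515 and 0.531), and RL with WSU (0.485 and 0.535). LY10 and TMD8 reached 0.453 and 0.493, LY8 and LY18 reached 0.421 and 0.488, and RIVA and U2932 reached 0.426 and 0.473. The lines least like the others, by the mean index over the other lines, were HLY1 (0.200 ± 0.0219, SD over the other lines), RCK8 (0.205 ± 0.0321), SUDHL7 (0.231 ± 0.0394) and PFEIFFER (0.261 ± 0.0377). Their order depended on the short Active Motif list of RCK8. With the Active Motif antibody the mean was 0.141 in RCK8, 0.160 in HLY1 and 0.200 in SUDHL7, and with the Diagenode antibody 0.241 in HLY1, 0.262 in SUDHL7 and 0.268 in RCK8. RL had the highest mean, 0.355 ± 0.0816. For lists of the same antibody in different lines, the mean index was 0.288 within a pool and 0.307 between pools, a difference that did not pass the threshold (two-sided permutation p = 0.076, 10000 permutations).

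**Figure D2:**
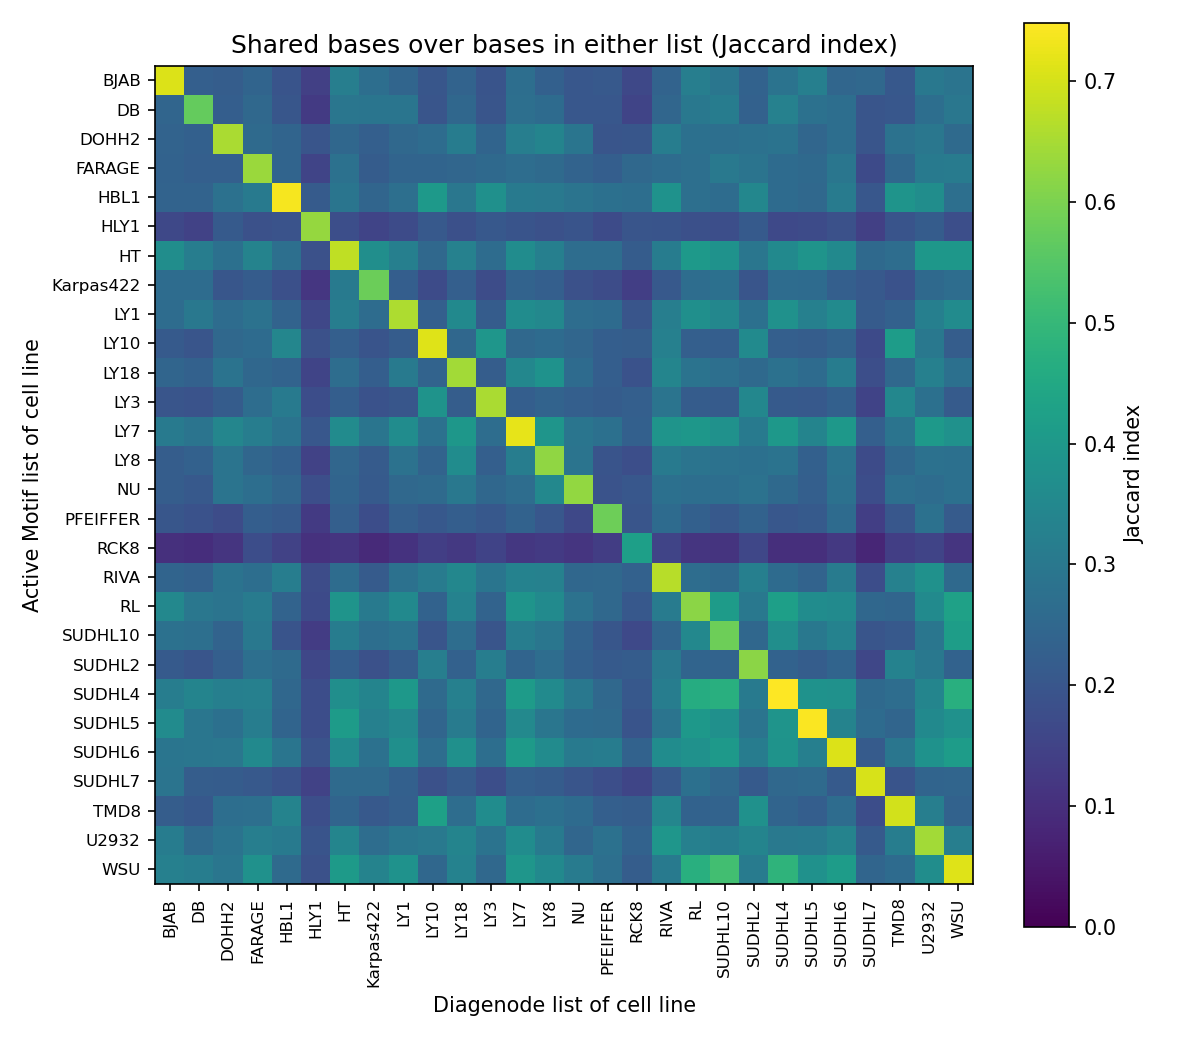
Jaccard index of every Active Motif list (vertical axis, by cell line) with every Diagenode list (horizontal axis, by cell line), as colour from 0 upwards. The diagonal holds the same-line pairs, between 0.422 and 0.748, and the dark rows and columns include HLY1 and RCK8.

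The third comparison asked which regions one antibody detected more often than the other in the same lines. Merging gave 188406 regions, of which 9475 had at least 6 lines with a peak from only one antibody. In the exact McNemar test with Benjamini-Hochberg adjustment, 8728 regions were detected more often with the Diagenode antibody and 177 with the Active Motif antibody. When every list was reduced to its 16316 widest peaks on the chromosomes that all lists hold, the counts were 4195 and 1019, so the Diagenode share of the calls was 80.5% against 98.0% with full lists. The other alternatives gave 5120 to 9062 Diagenode and 78 to 228 Active Motif calls. Regions called for the Diagenode antibody had a median width of 1026 bp, and those called for the Active Motif antibody 1538 bp.

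In 48 regions every measured line had a Diagenode peak and no line an Active Motif peak, while no region showed the reverse. The 5 widest with 28 such lines were on chromosome 14 (75178986 to 75180437), chromosome 10 (43047047 to 43048267), chromosome 4 (48907952 to 48909138), chromosome 22 (31608142 to 31609149) and chromosome 1 (55229174 to 55230177), each with an adjusted p of 1.1e-06 in the exact McNemar test. The largest lean to the Active Motif antibody was 12 lines, on chromosome 17 (42277154 to 42277576), where 25 lines had an Active Motif and 13 a Diagenode peak (adjusted p = 0.0011, exact McNemar test). The next were a region on chromosome 19 (49994722 to 49996981, 16 against 5 lines), a region on chromosome 7 (25156843 to 25158380, 15 against 4), a second region on chromosome 17 (45740657 to 45741858, 23 against 12) and a region on chromosome 10 (4374109 to 4376874, 15 against 5). In these 5 regions no line had a Diagenode peak without an Active Motif peak.

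The fourth comparison asked how widely regions were shared when a line counted only with peaks from both antibodies. Such detection was reached in at least 1 line by 118372 regions, and in no line by 70034. In exactly 1 line it was reached by 60690 regions (51.3% of the 118372), and in every measured line by 2357 (1.99%). The counts fell from 15619 regions in 2 lines to 626 in 20 lines and rose again to 2125 in 28 lines. Merging widens regions with peaks in more lists, so their length was compared by the bases that the peaks of a line covered in them. The median in a line averaged 1540 ± 179 bp for regions of every line and 396 ± 75.4 bp for regions of that line alone (SD, n = 28), and was larger for the former in 28 of 28 lines. These values sum all peaks of a line in a region. Wider regions can hold more than 1 peak of a line, so an effect of merging may remain in them. A line held 19477 ± 4040 regions (SD, n = 28), of which the regions of every line made up 12.5 ± 2.52% and regions of that line alone 10.2 ± 8.65%. HLY1 and SUDHL7 stood at the upper end, with 10868 regions (37.6%) and 8770 regions (32.1%) of their own. U2932 stood at the lower end, with 328 (1.95%). By chromosome, the share of detected regions found in every line was highest on chromosome 19 (5.12%) and lowest on chromosome 18 (1.14%) and chromosome 8 (1.15%).

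The counts depended on the rules for peaks, merging and detection, and moved in both directions. They were 7084 regions in every line and 104734 in 1 line when a peak from either antibody sufficed, and 49 and 65028 when peaks had to cover the larger part of a region. They were 794 and 32223 with peaks down to the median width of each list, 944 and 25968 with lists of equal length, and 2314 and 30526 when peaks were merged over gaps up to 1 kb.

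Among the regions of every line, the largest minimum coverage over lines was on chromosome 17 (56404814 to 56418526), where peaks covered 12157 ± 621 bp (SD, n = 28) and at least 10657 bp in each line. Next were regions on chromosome 16 (81846725 to 81873053, 22239 ± 3713 bp) and chromosome 11 (65182009 to 65201091, 14115 ± 2523 bp). The longest region of 1 line was in RCK8 on chromosome 2 (106472830 to 106497246), with 23499 bp covered and no peak in any list of another line.

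**Figure D3:**
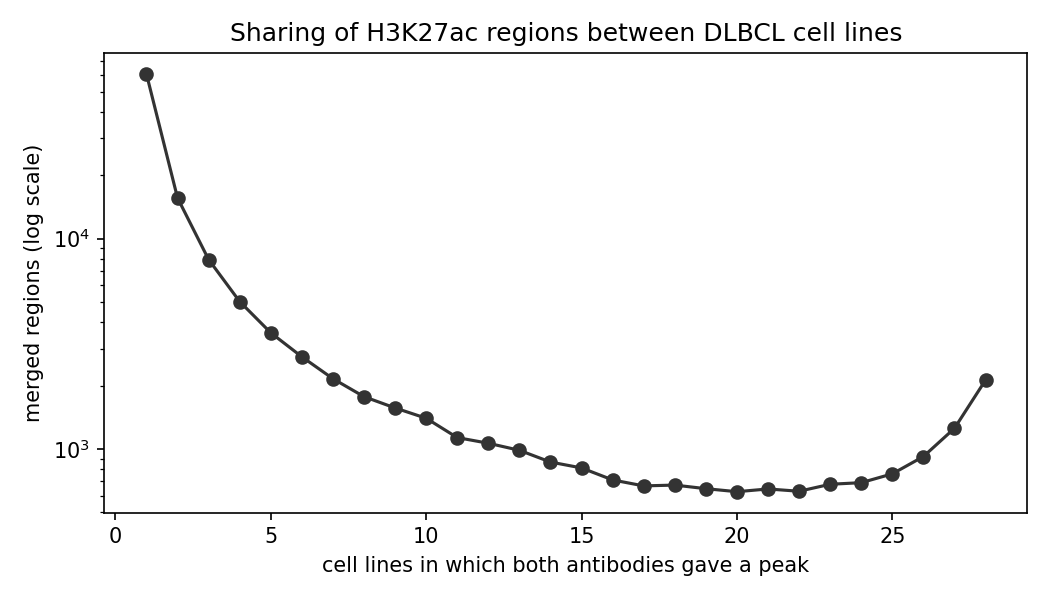
Number of merged regions (log scale) by the number of cell lines in which both antibodies gave a peak. Counts fall from 60690 in 1 line to 626 in 20 lines and rise to 2125 in 28 lines.

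The fifth comparison asked where the covered lengths of the lines agreed between the antibodies, so that the same lines were high or low with both. Of 63684 windows of 20 kb with a peak in any list, 51276 passed the threshold of the pairing test (one-sided permutation, Benjamini-Hochberg). In the 22284 windows with peaks from both antibodies in at least 5 lines, 21897 passed (98.3%), and in the 2418 windows with peaks from both antibodies in every measured line, 2324 passed (96.1%). Of the passing windows, 16056 had both antibodies in only 1 line, where the p of 0.036 reflects that 1 line of 28. Without the 3 lines with a library named EP, that p is 0.04 for 1 line of 25 and the count was 33641.

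The 20 windows with the largest SD between lines each had p = 1e-05 and an adjusted p of 3.6e-05 in that permutation test. The window at the top lay on chromosome 3 (187680001 to 187700000), with 12464 ± 9347 bp covered (SD, n = 28 lines) against an SD of 355 bp between antibodies. Peaks of both antibodies covered it fully in HT, LY1, PFEIFFER, RL, SUDHL4, SUDHL5, SUDHL6 and WSU, and it was without peaks in DOHH2, HLY1, NU, RCK8, SUDHL2 and TMD8. Covered length is bounded by 0 and 20000 bp, so the lines at these bounds add no difference to the SD between antibodies. The neighbouring windows from 187640001 to 187680000 were also among the 20, with 8 lines at 0 in the second and 6 in the first. This stretch held 13 of the 25 widest peaks of all lists, from 8 lines and 37065 to 58108 bp wide. The widest was the Diagenode peak of SUDHL5 from 187643964 to 187702071, and the Active Motif peak of the same line spanned 57966 bp.

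**Figure D4:**
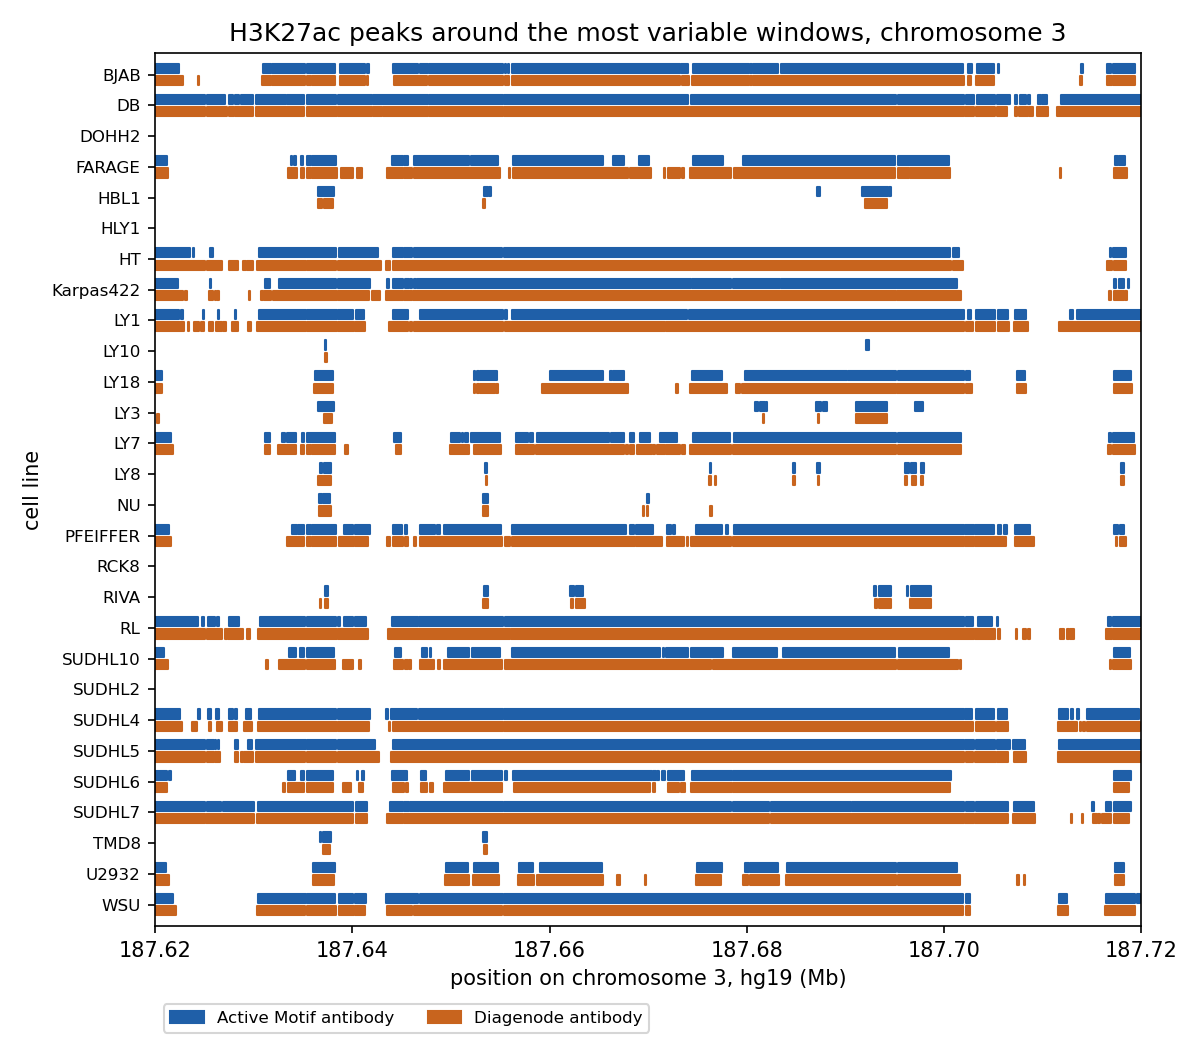
Peaks on chromosome 3 from 187620001 to 187720000 (hg19, horizontal axis in Mb) in each of 28 cell lines (vertical axis), with Active Motif peaks in blue and Diagenode peaks in orange. Peaks fill most of the span in lines such as DB, RL and SUDHL5, and no peak is drawn in DOHH2, HLY1, RCK8 and SUDHL2.

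A pair of windows on chromosome 1 (226840001 to 226880000) was covered in most lines, with 11246 ± 8277 and 11631 ± 8222 bp (SD, n = 28), and lay within the 50411-bp Active Motif peak of SUDHL5 (226837588 to 226887998). TMD8 had no covered base in the first of them. Windows on chromosome 2 (89140001 to 89160000) and chromosome 22 (23220001 to 23240000) were at 0 in 6 and 9 lines. Of these lines, DB, HLY1, LY18, LY3 and LY8 were at 0 in both. On chromosome 7, a window at 55580001 to 55600000 was highest in LY10, LY3 and HBL1, and one at 101500001 to 101520000 in SUDHL6, BJAB and WSU. A window on chromosome 12 (11900001 to 11920000) was highest in LY10, LY3 and PFEIFFER and at 0 in DB, HT, Karpas422, RCK8, SUDHL10, SUDHL7 and WSU. A window on chromosome 10 (126220001 to 126240000) was highest in Karpas422, SUDHL5 and WSU and at 0 in 9 lines, which included DOHH2, HBL1, HLY1, LY10, LY3 and TMD8.

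The remaining windows were at 16480001 on chromosome 3, 82000001 and 8700001 on chromosome 8, 10340001 on chromosome 19, 121320001 on chromosome 11, 22940001 and 94420001 on chromosome 14, 53100001 on chromosome 18 and 56040001 on chromosome 20. Their SD between lines ran from 6994 to 8217 bp, against 476 to 1195 bp between antibodies. HLY1 had no covered base in 11 of the 20 windows and RCK8 in 10. BJAB, LY7, SUDHL4 and U2932 had covered bases in each of the 20.

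**Figure D5:**
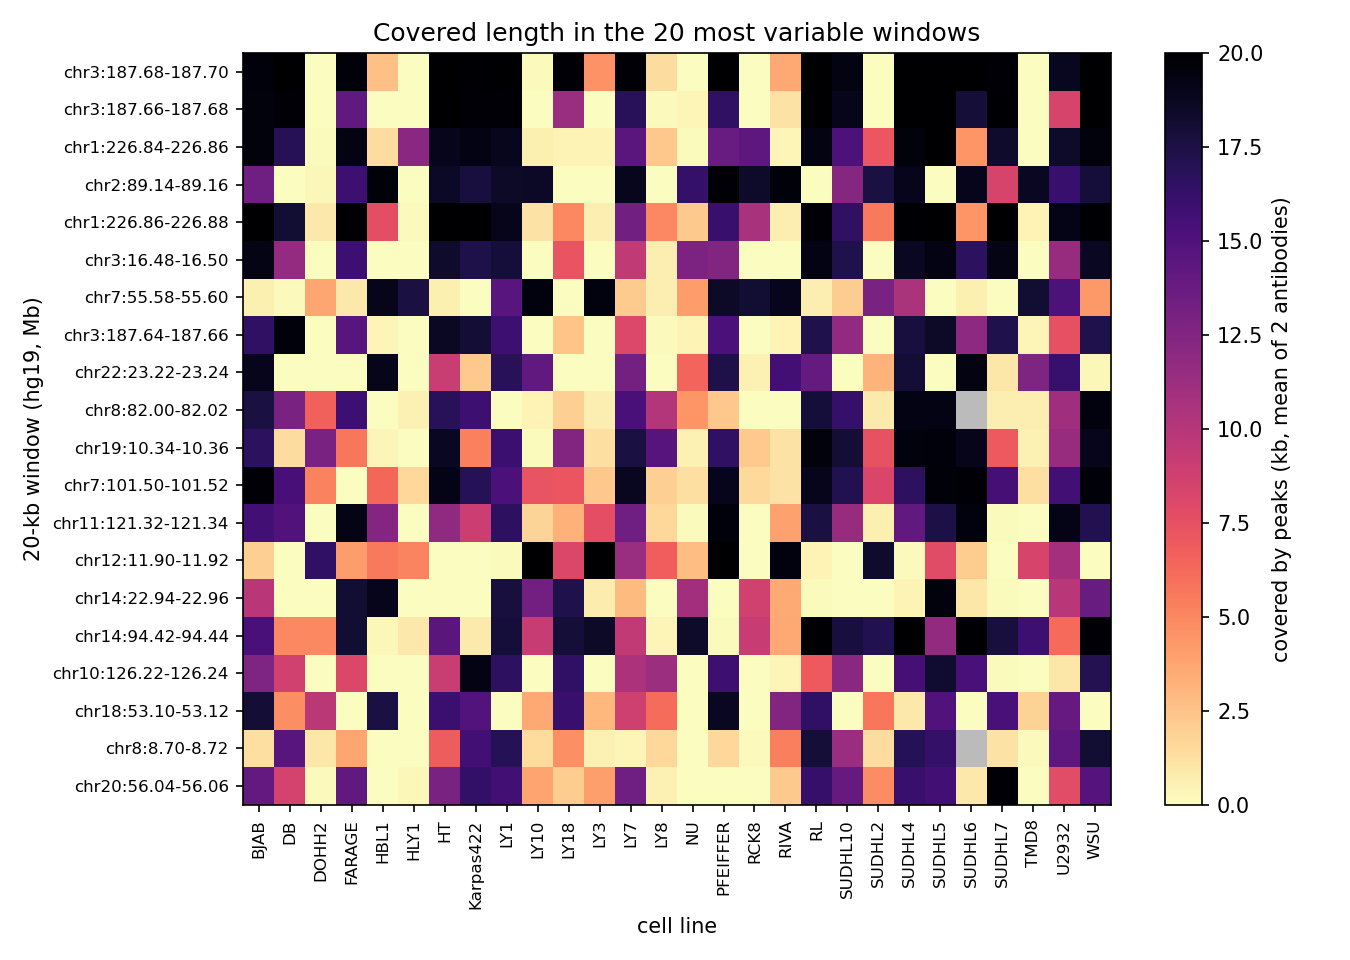
Covered length (kb, mean of the 2 antibodies, colour from 0 to 20) in the 20 windows of 20 kb with the largest SD between lines (vertical axis, hg19) for each cell line (horizontal axis); grey marks windows on chromosome 8 not measured in SUDHL6. HLY1 is at 0 in 11 windows and U2932 in none.

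The sixth comparison asked how many clustered domains of acetylation the lines held and shared. Clustered domains resemble super-enhancers, which are dense groups of enhancers near genes of cell identity, but were defined here from peak positions without read signal. A line held 630.0 ± 153 domains with both antibodies (SD, n = 28), from 319 in DB to 1006 in SUDHL4. The cut-off was set for each list and ran from 4851 to 12213 covered bp. It was 12195 bp (Active Motif) and 11912 bp (Diagenode) in DB, and 8359 and 8486 bp in SUDHL4. The counts therefore do not compare the lines at one cut-off. Domains made up 34.8 ± 4.72% of the covered sequence of a list. They formed 3973 loci, of which 1826 (46.0%) occurred in 1 line, 321 in at least 14 lines, and 7 in every measured line, 1 of them on a chromosome measured in 27 lines. HLY1 and SUDHL7 held 297 and 227 loci of their own, and U2932 held 13.

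The 10 loci found in the most lines were led by 6 with a domain in 28 of 28 lines. These lay on chromosome 11 (9584102 to 9787463, and 65170338 to 65278347), chromosome 16 (81803546 to 81908918), chromosome 7 (50300066 to 50370553), chromosome 17 (56395145 to 56460450) and chromosome 14 (106023808 to 106074886). The first of them carried 57173 ± 22387 bp of peaks (SD, n = 28) and the locus on chromosome 16 carried 45311 ± 10743 bp, both most in PFEIFFER. A locus joins overlapping domains over lines, so lines counted at 1 locus need not share a base. In the first locus, neither list of HLY1 held a peak from 9700146 to 9770706. The locus on chromosome 17 was the most even, at 17389 ± 2116 bp. The other 4 lacked a domain in 1 line, which was RCK8 for the loci on chromosome 3 (186693394 to 186840509), chromosome 1 (198564706 to 198672735) and chromosome 17 (37893696 to 37979384), and DB for the locus on chromosome 15 (75053858 to 75166037). RCK8 had 382 domains with its short Active Motif list and 809 with the Diagenode list, and at the locus on chromosome 3 its Diagenode list did hold a domain. At the other 3 loci neither list of the line held one. At the locus on chromosome 15, DB still carried 19874 bp (Active Motif) and 17948 bp (Diagenode) of peaks. A line counted there carried only 13172.5 bp (mean of the antibodies). The cut-offs of the DB lists, 12195 and 11912 bp, were near the top of the range. DB therefore lacked a domain there without having the least covered sequence. At the loci without a domain in RCK8, that line did have the least.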

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

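The antibody difference had the opposite sign in some lines from that in most. These differences between lines were not tested, since each line has 1 library per antibody. In covered sequence, Diagenode minus Active Motif was -1.04 Mb in HLY1, while the other 27 lines had positive values. In median peak width it was -3 bp in BJAB, -23 bp in HLY1 and -19 bp in SUDHL4. In the number of clustered domains per list, it was -86 in HBL1, -25 in HLY1, -30 in NU, -7 in SUDHL6, -37 in TMD8 and -134 in U2932, against a mean of 82.9 over all lines. No biological explanation was tested for these values.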

How the results depend on the processing

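Of 71 recomputed values, which include those without SUDHL6 but not the removal of each line in turn, 53 were unchanged and 18 moved. Unchanged means the same direction and side of the threshold for tested differences, within 1.5 times the reported value for counts, and within 1 SD over lines for domains per line. Alternatives with 100-kb windows or without SUDHL6, and the removal of each line in turn, were chosen after the data were seen. None reversed a direction. The antibody differences in peaks and covered sequence and the overlap difference kept direction and significance in every alternative run for them. With the antibody labels permuted over all libraries instead of paired by line (no replicate block), the differences of 8486 peaks and 6.94 Mb had p = 2e-05 and 4e-05, and no call changed.

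Keeping peaks down to the median width of each list gave 794 regions in every line and 32223 in 1 line. Equal list lengths gave 944 and 25968, with 4195 Diagenode and 1019 Active Motif calls, 446 domains per line and 32512 windows. These settings remove peaks by construction. Merging over gaps up to 1 kb gave 5120 Diagenode calls and 30526 regions in 1 line, from fewer and longer regions. Requiring the larger part of a region to be covered gave 49 regions in every line and 78 Active Motif calls. Detection by either antibody gave 7084 regions in every line, 104734 in 1 line and 796 domains per line. Without the 3 lines with a library named EP, there were 107 Active Motif calls, the cause of which was not tested, and 33641 windows, where the p reached by 1 line of 25 rose to 0.04. Of windows of 100 kb, which are fewer, 20486 passed.

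Leaving out each line in turn gave 8129 to 8696 peaks, 6.51 to 7.23 Mb, an overlap difference of 0.383 to 0.394, 8340 to 8683 Diagenode and 139 to 178 Active Motif calls, 2357 to 2855 regions in every line, 52885 to 61214 in 1 line, and 289 to 315 loci in at least 14 lines. The window test was not run this way. Also not run were the pool alternative for overlap and regions, because 2 lines had both libraries in one pool, equal lengths for the peak count, which fix it, ranking by score, and those needing gene positions. Unknown read depth limits every count of regions.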

Other observations

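The tests of the input library and of random splits and the bootstrap intervals were chosen after the results were seen, and the other tests below before. The patterns themselves were noticed in these data, the definition of a run of missing regions was set after similar runs had been seen, and the requirement that an interval clear the opposite bound was added after the correlations were known.

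Beyond the comparisons of the report, the lines differed in how the covered sequence fell on chromosomes. Shares are given as a percentage of the covered sequence on the 20 chromosomes that all lists hold, which leaves out chromosomes 8, 9 and X from the denominator. Chromosome 18 varied most relative to its mean, with a share of 2.42 ± 0.535% (SD, n = 28), a coefficient of variation of 22.1% and an SD of 0.0574 between antibodies. U2932 (3.38%), RIVA (3.38%), LY3 (3.21%), HBL1 (3.20%), TMD8 (3.13%), LY10 (3.07%) and LY18 (2.92%) had the highest shares and RL (1.51%) the lowest. On the other chromosomes, the highest values relative to the median of the lines were chromosome 13 in BJAB (3.80% against a median of 2.51%), chromosome X in SUDHL7 (4.39% against 3.01%, n = 27), chromosome 20 in PFEIFFER (4.27% against 3.12%), chromosome 7 in DB (7.89% against 5.82%) and chromosome 4 in HLY1 (6.27% against 4.63%). The lowest was chromosome 21 in Karpas422 (0.927% against 1.32%).

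Shared regions that a line lacked altogether were long ones. Among 5145 regions detected with both antibodies in all measured lines but at most 3, the 4161 with a peak in every line covered a median of 1358 bp where present. The 579, 303 and 102 regions with no peak of either antibody in 1, 2 or 3 lines covered 2068, 2597 and 3224 bp. The choice of regions may contribute to this order. A region with no peak in 3 lines had to have peaks of both antibodies in all other measured lines. A region with a peak in every line could have up to 3 lines with only 1 antibody. No explanation was tested for this order.

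Regions seen only with the Diagenode antibody were examined further. Regions with a Diagenode peak in each of 14 alternate lines and no Active Motif peak there were read in the other 14 lines, in both directions, from 106 and 141 regions. Diagenode lists held 96.1 ± 4.22% of them (SD, n = 28) and at least 80.1%, and Active Motif lists 5.50 ± 8.07%. Shorter lists alone do not account for this, since the 14 Active Motif lists that covered at least the 26.2 Mb of the smallest Diagenode list held at most 36.2%, in HBL1. That Diagenode list is the one of SUDHL6 on 20 chromosomes, and the 26.4 Mb of LY18, the smallest on all 23, would select the same 14 lists. The highest Active Motif shares were in HBL1 and HLY1 (23.6%), whose 2 lists covered nearly equal sequence. SUDHL4, with nearly equal lists too, held 9.43%. A contribution of list length relative to the other list of the line is therefore not excluded. The library pool does not account for the pattern either, since the 8 Active Motif libraries of pools with both antibodies held at most 11.3%, nor the input, which was shared by both lists in 28 of 28 lines. The antibody itself cannot be separated from unknown read depth or other steps that went with it, and no biological explanation was tested. Of 100 assignments of the antibody labels within lines, the real one gave 8905 called regions and the highest of the others gave 0, so 1 of 100 was as large. The test of each region rests on the same exchange of labels, so this excludes chance only as dependence between regions and is no separate support for the count.

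Some lines lacked runs of neighbouring shared regions. With both antibodies silent over at least 4 consecutive shared regions, 12 runs were found in 8 lines, and 1000 shuffles of the misses within a line and chromosome gave at most 2 (p = 0.001). HLY1 had 3 runs, LY8 had 2 of 5 regions each, on chromosome 1 (149782225 to 149860947) and chromosome 19 (6575160 to 6804723), and RCK8 had 2. The regions of the runs were not short as a set, with a median percentile of 77.7 for covered length in the other lines. SUDHL5 on chromosome 17 (12.5) and FARAGE on chromosome 2 (27.3) were the low ones. The 1441 isolated misses had a similar median percentile of 75.6, so the high value is not particular to the runs. Missed shared regions were long in general, so this comparison could hardly have found weak ones. The lists also hold no peak height, so weak signal is not excluded. Loss of the whole span of DNA is excluded for 3 runs, which held peaks of the same line, and cannot be told apart from an unacetylated span for the other 9, because lists show no reads.

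The share of chromosome 18 was weighed against 2 explanations. Its correlation with the covered sequence of the lists was -0.135 over 28 lines (bootstrap 95% interval -0.416 to 0.154, Spearman -0.0826, permutation p = 0.50 and 0.67, adjusted 0.50 and 0.67), and -0.183 without the 2 most extreme lines. Over all lines, the share therefore showed no strong relation with list length. Within 6 pools of 6 or more libraries this correlation ran from -0.911, in Diagenode pool 6 (7 libraries), to 0.209, so a contribution of list length is not excluded. If a whole-chromosome change such as extra copies were the source, the parts before and after position 47813146, which hold equal covered sequence, should rise together. Their correlation was 0.281 (interval -0.0617 to 0.571, Spearman 0.281, permutation p = 0.15 for both, adjusted 0.30), 0.280 without the 2 most extreme lines, and -0.347 to 0.618 within pools, which lies on the side predicted for a few strong loci (below 0.3). Its interval keeps both open, so a few strong loci and a whole-chromosome change cannot be told apart with 28 lines. Copy number was not analysed here.

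For the window count, 100 pairings of the lists of the 2 antibodies were compared on the 55705 windows measured in every line, with 1000 resamples each. The real pairing gave 41955 windows past the threshold and the highest of the others gave 0, so 1 of 100 was as large. The test of each window draws the same kind of pairing, so this excludes chance only as dependence between windows and is no separate support for the count.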
